A study of Picosynechococcus sp. PCC 7002 with 6 samples.

How the data were processed

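Total RNA of the unicellular cyanobacterium Picosynechococcus (Synechococcus) sp. PCC 7002 was sequenced on the SOLiD platform, per the labels' protocols. The cells were wild type and grew in a turbidostat, a continuous culture that is diluted to hold cell density constant. There were 6 libraries, 1 for each irradiance. The levels, in µmol photons per square metre per second, were 33, 98, 164, then 395, 610 and finally 760. The light came at 630 and 680 nm. Both wavelengths had equal parts in the labels of the 4 libraries from 33 to 395, whereas the 630 nm part was larger at 610 and 760. Whether the 6 libraries came from separate cultures or from 1 culture moved from level to level is not stated in the sources used here.

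The deposited table gives 1 score per gene and library, made by the authors as a relative expression value whose unit no header or label names. The aligner, the counting method, the genome build and the normalization are not given in the sources used here. All values are whole numbers from 1 to 31217. In each library more genes stand at 1 than at 2 (52 against 28 at 33, for example), and no gene is listed at 0. Over the 1062 genes above 50 in every library, the median-of-ratios factors of the libraries lie between 0.976 and 1.02. Over all genes they run from 0.925 at 164 to 1.12 at 610. The values were taken as already brought to about one scale and rounded, and not as raw reads, on the factors of the genes above 50. Sequencing depth is unknown, so no counting interval is given, and count models were not applied. Whether values were divided by gene length is not known.

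Genes are identified by locus tag. None of the 3187 tags matched the reference gene table, which uses another tag series, so 0 tags could be given a gene name. Of the 35 functional gene lists fixed before the data were examined, 0 could be filled, and the rule for naming genes could be applied only in part. That rule took, among genes past the threshold with a mean at or above the median gene (41.7), those with the largest slopes and a known product. Without products, the 2 tags with the largest slope in each direction are named, and no tag is named for the other comparisons. The tags fall into 7 letter series. Series A holds 2824 tags and was taken as the chromosome, and series B to G hold 3, 17, 30, 39, 109 and 165 tags and were taken as the 6 plasmids. The 7 sequences of the reference assembly hold 2894, 5, 17, 35, 42, 115 and 171 genes, in the same order of size.

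The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with moderated variances that follow the mean and a robust fit. It tested the slope on log2 irradiance over all 6 libraries, with 4 residual degrees of freedom, at a Benjamini-Hochberg adjusted p of 0.05. Fold changes on this scale understate the change of genes with low values. A minimum mean of 1 removed 0 genes. Since each level has 1 library, the error of a slope is the scatter of the libraries about a line and holds no replicate error at a level, and p-values measure only the spread between these libraries. A second fit added the square of log2 irradiance, with 3 residual degrees of freedom, and tested that term as a bend. The tag series with at least 5 genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The share of each library's summed values taken by each series was related to log2 irradiance with exact permutation over all 720 orders (Python 3.11.15, scipy 1.17.1), two-sided. Folds between single libraries carry no test. A gene counted as at least 2-fold apart when (value + 1) differed by a factor of 2 and the higher value was at least 10.

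In data simulated with the residual scatter of the trend fit over 3187 genes, planted slopes of 0.25, 0.5 and 1 were recovered in 40%, 82% and 98% of cases, with 10 false calls. Planted bends of 0.4 were recovered in 91% of cases, with 4 false calls. Both were planted only in genes with a mean at or above the median gene, with scatter drawn independently for each gene and library. Recovery among weaker genes and false calls from deviations shared within a library were thus not measured. The planted bend was also larger than the median called bend (0.21 upward and -0.19 downward). The alternatives were other scalings of the libraries, filters, pseudocounts, limma without both the variance trend and the robust fit, irradiance on a linear or rank scale, a term for unequal light, the 4 libraries with equal light alone, and leaving out each library in turn. Quantile normalization, a minimum mean of 100, the share of series G without its run of 8 falling tags and the estimated correlation for series C and D with libraries left out were added after the data had been seen. The design had foreseen a count model and trimmed-mean scaling in case the values were counts. As they were not taken as counts, the values were used as deposited.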

Results

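Transcript levels were measured at 6 steady-state irradiances between 33 and 760 µmol photons per square metre per second, to describe how expression in a fast-growing marine cyanobacterium follows light supply. All irradiances below are in this unit. The table held 3187 locus tags, of which 2824 belonged to series A, taken as the chromosome, and 363 to the 6 plasmid series B to G. The summed values fell at each step of irradiance. They were 813751 at 33, 775156 at 98, 765737 at 164, 760705 at 395, 749598 at 610 and 735695 at 760. Effects of the totals and of irradiance thus cannot be told apart, and the main fit did not scale to these totals. With scaling to equal totals the median slope of all tags was 0.035, against 0.008 in the main fit. The depth behind the totals is unknown, and each irradiance had 1 library, so no value has a replicate error. Light at 610 and 760 also held a larger 630 nm part (125 to 60 and 170 to 60) than at the lower levels, where both wavelengths were equal, so irradiance and light ratio change together there.

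Across genes, Pearson's r of log2 values was 0.971 between 395 and 760, 0.969 between 98 and 164, and 0.905 between 33 and 610, the lowest of the 15 pairs. Genes are not independent replicates. The library at 610 differed from its neighbours among weakly expressed tags. It listed 72 tags at 5 or below, against 203 to 321 in the other libraries, and its 10th percentile was 12, against 5 to 8. Of the 800 tags in the lowest quartile of mean value, 48.5% had their highest value at 610, compared with 14.9% of the 796 tags in the highest quartile. Among tags below the median value, the value at 610 exceeded the mean of 395 and 760 by a median of 5 units in series A, 65 in series C, 15.2 in series D and 24.5 in series E. In plasmid series F and G the excess was 4.5 and 4 units.

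**Figure D1:**
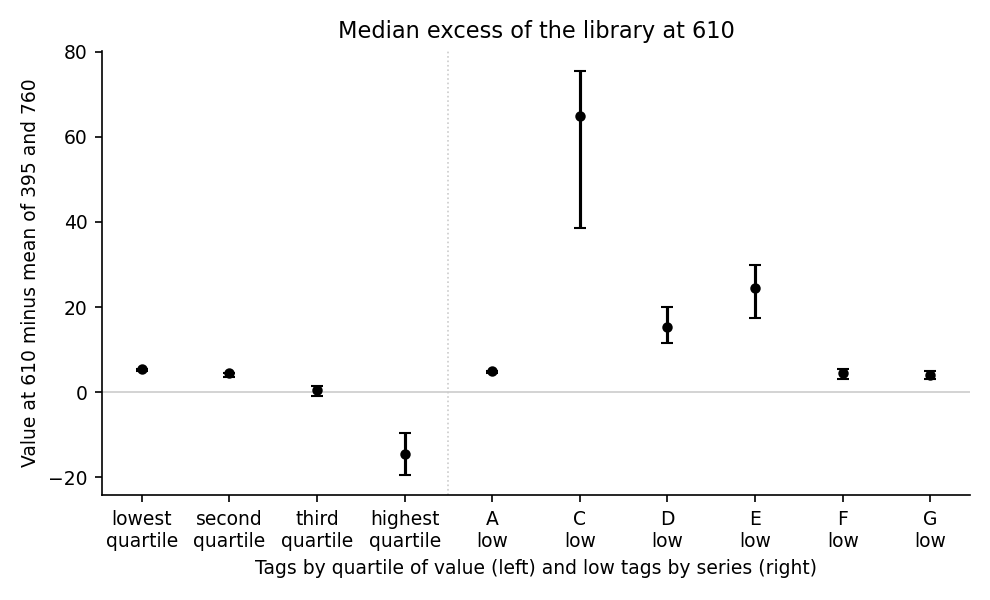
Median difference between the value at 610 and the mean of the values at 395 and 760, in deposited units, for tags by quartile of value (left) and for tags below the median value by series (right). Bars are 95% bootstrap intervals over tags. The excess is 5.5 units in the lowest quartile and 65 units among the 9 low tags of series C.

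A slope on log2 irradiance was called in 163 tags, 77 rising and 86 falling. The slope is that of a fitted line and does not mean a change at every step. Without limma's variance trend and robust fit, 11 tags rose and 26 fell, and on ranks of irradiance 44 rose and 51 fell. Among called tags of at least median value, the steepest rising slopes were those of SYNPCC7002_A0814, from 108 at 33 to 825 at 760 (7.64-fold), and SYNPCC7002_A2662, from 114 to 742 (6.51-fold). The steepest falling slopes among these tags were those of SYNPCC7002_A1476, from 431 to 19, and of the plasmid tag SYNPCC7002_G0036, from 1142 to 47. A0814 passed through 176, 205, 592 and 499 at the levels between, and A2662 through 271, 348, 659 and 520, so both stood lower at 610 than at 395. A1476 was already at 11 at 164 and reached 2 at 395, whereas G0036 was at 468 at 164 and at 53 at 395.

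The slopes, in log2 units per doubling of irradiance over 6 libraries, were 0.64 ± 0.08 (SE) for A0814, 0.56 ± 0.07 for A2662, -1.30 ± 0.29 for A1476 and -1.29 ± 0.16 for G0036. Their limma adjusted p-values were 0.0050, 0.0050, 0.036 and 0.0050. The call for A1476 did not hold without the library at 33 (limma adjusted p = 0.227), 98 (0.086), 395 (0.069) or 610 (0.126), where its slope lay between -1.03 and -1.31, nor on linear irradiance (0.241), on ranks (0.099), among tags with a mean of at least 100 (0.088) or without limma's variance trend and robust fit (0.118); the other 3 tags stayed past the threshold with any 1 library left out. A2662 missed it on linear irradiance (limma adjusted p = 0.052), and A0814 (0.059) and G0036 (0.068) missed it with the 4 libraries of equal light alone, at slopes of 0.65 and -1.19. With a term for unequal light all 4 tags passed it (limma adjusted p = 0.028, 0.0074, 0.017 and 0.043 in the order above). The slope of A1476 was -2.06 with that term and -2.11 with equal light alone. Calls that held say little, since the 4 tags had been picked for steep called slopes in the same libraries. Among the 77 rising tags the median slope was 0.34 and the largest 0.87. Among the 86 falling tags the median was -0.43 and the steepest -1.30. In all, 685 tags had an unadjusted p under 0.05, against a mean of 159 under chance. Tags are not independent, so a chance count can lie far from that mean.

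**Figure D2:**
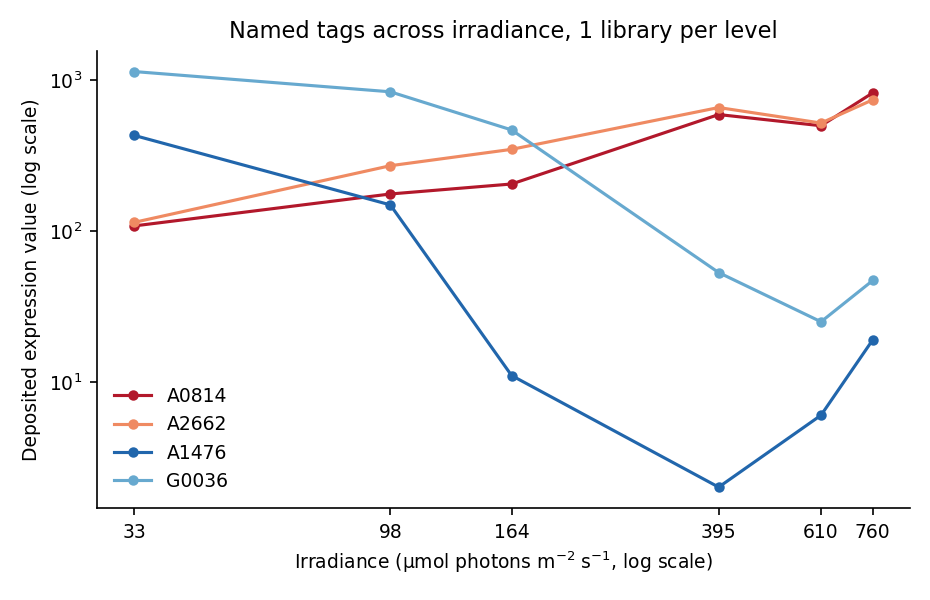
Deposited expression values (log scale) of the 2 rising and 2 falling named tags against irradiance (log scale), 1 library per point. A0814 and A2662 lie between 108 and 825, and G0036 drops from 468 at 164 to 53 at 395.

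The number of calls depended on single libraries. Rising and falling tags numbered 177 and 139 without the library at 33, 26 and 36 without 98, 110 and 122 without 164, 11 and 27 without 395, 21 and 39 without 610, and 29 and 51 without 760. All 163 tags kept the sign of their slope in each of these fits. That says little, since they had been picked for strong slopes in the same libraries. Those of the 163 called again numbered 88 without 33, 60 without 98 and 160 without 164. Without 395, 610 and 760 they numbered 38, 53 and 68. Scaling the libraries to equal totals gave 136 rising and 80 falling tags. With the 4 libraries of equal light alone, 9 tags rose and 28 fell, and 25 of these 37 were among the 163. With a term for unequal light, 32 rose and 60 fell, and 55 of these 92 were among the 163. A strict order over the 6 levels was seen in 28 rising and 30 falling tags, against 4.43 of each that a random order would give, and 14 and 21 of them were among the 163.

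The plasmid series held more than their part of the falling tags. Of 363 plasmid tags 24 fell (6.61%), compared with 62 of 2824 tags of series A (2.20%), an odds ratio of 3.15 (95% interval 1.86 to 5.20; Fisher's exact test, two-sided, p = 1.66e-05, adjusted over 4 such tests p = 6.63e-05). Of the plasmid tags 1.65% rose, against 2.51% of series A, an odds ratio of 0.65 (0.23 to 1.51; Fisher's exact test, p = 0.465, adjusted 0.62). With 1 library left out, the odds ratio for falling tags lay between 2.04 (without 33) and 5.02 (without 610). It was 5.48 with a term for unequal light and 10.8 with equal light alone. Of the falling plasmid tags 8 were consecutive tags of series G. Without this run, 16 of 355 plasmid tags fell, the odds ratio was 2.10 and the unadjusted p was 0.016 by Fisher's exact test. The 8 tags had been picked as falling, so this is arithmetic and no test. Tags are not independent, so these p-values are too small.

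In series F, 11 of 109 tags fell and 0 rose over all genes tested, and 21 were called when adjusted over the list alone. Its median slope was -0.14, and camera placed it below the other tags (adjusted p = 2.9e-06), but not with an estimated correlation (adjusted p = 0.86). Its difference from the other tags, -0.15, was -0.31 without the library at 33, -0.11 without 98 and -0.09 with a pseudocount of 10. The rotation test fry in limma, which asks whether the tags of a series move one way on balance, gave a limma adjusted p of 0.34 for series F. Series G had 11 falling and 6 rising tags of 165, with 21 called when adjusted over the list alone, and a median slope of -0.01 (camera adjusted p = 0.43). Its difference from the other tags, -0.015, was 0.029 without the library at 760. Among tags with a mean of at least 100 it was -0.47 (camera adjusted p = 0.044). In series A, 71 tags rose and 62 fell, with 129 adjusted over the list alone. Camera placed series A above the plasmid tags by a median of 0.04 (adjusted p = 0.040), again not with an estimated correlation (adjusted p = 0.86), nor without the library at 98 (0.079), 395 (0.064) or 760 (0.67), with a term for unequal light (0.081, at a median difference of 0.067) or with the 4 libraries of equal light alone (0.069, at 0.052). With 1 library left out this difference ranged from 0.010 without 760 to 0.101 without 33. Series C, with 0 called of 17 tags, had a median slope of 0.13 (camera adjusted p = 0.29). Without the library at 760 it passed (camera adjusted p = 0.038), but not with an estimated correlation (adjusted p = 0.95). Its difference from the other tags, 0.12, rested on the library at 610: it was 0.003 without that library, 0.008 with equal light alone and -0.010 with a term for unequal light. Series D had 2 falling tags of 30, both also called when adjusted over the list alone, and a median slope of -0.03 (camera adjusted p = 0.40). Without the library at 610, series D lay 0.19 below the other tags (camera adjusted p = 0.00064), and with the 4 libraries of equal light alone 0.15 below (camera adjusted p = 0.031). Neither call held with an estimated correlation (adjusted p = 0.18 and 0.56), and the difference was 0.05 above the other tags without the library at 760 and 0.01 above without 33. Series E, with 0 called of 39 tags, had a median slope of 0.03 (camera adjusted p = 0.68). Series B has 3 tags and was not tested.

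**Figure D3:**
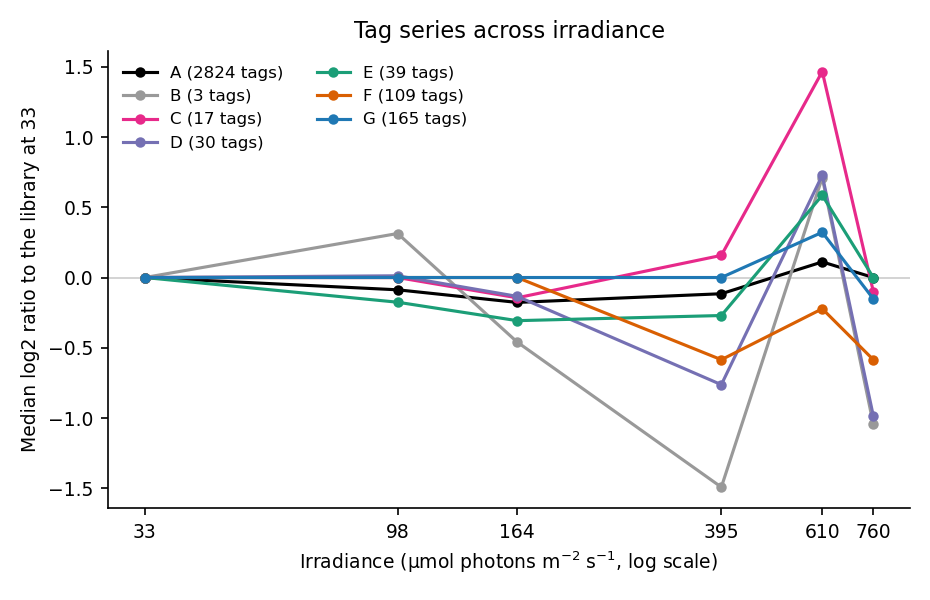
Median over the tags of each series of the log2 ratio to the library at 33, against irradiance (log scale). Series F lies at -0.58 at 395 and 760, and series C reaches 1.47 at 610 and returns to -0.10 at 760.

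The share of the summed values taken by series G fell from 1.22% at 33 to 1.06% at 98, 0.878% at 164, 0.639% at 395, 0.693% at 610 and 0.611% at 760. Pearson's r with log2 irradiance was -0.976 (exact permutation p = 0.0042, adjusted over 9 relations 0.038) and Spearman's rho -0.943 (exact permutation p = 0.0167, adjusted 0.050). The run of 8 consecutive falling tags carried this fall: their summed values went from 5455 at 33 to 418 at 760, against 9954 and 4497 for the whole series. Without the run, the share of series G was 0.557% at 33, 0.65% at 164 and 0.555% at 760, which is arithmetic and no test, since the 8 tags had been picked as falling. The share of series A was 96.5% at 33 and 97.4% at 760. Because shares add up to 100%, this mirrors the plasmid shares and is no separate result. It gave r = 0.930 (exact permutation p = 0.0097, adjusted 0.044, or 0.069 with the 10 most abundant tags left out of the total) and rho = 0.943 (exact permutation p = 0.0167, adjusted 0.050). Without the libraries at 33 and 760, farthest from the median irradiance, r was -0.936 for series G and 0.904 for series A. The 100 most abundant tags of each library took 59.5% of the values at 33 and 53.3% at 760, with rho = -1 (exact permutation p = 0.0028, the smallest this test can give, adjusted 0.025) and r = -0.848 (exact permutation p = 0.024, adjusted 0.071). The summed values of the libraries fell in the same order. Without the libraries at 33 and 760 the r of the 100 most abundant tags was -0.961. For series F the share went from 0.715% to 0.50% (r = -0.839, exact permutation p = 0.069, adjusted 0.11; rho = -0.829, exact permutation p = 0.058, adjusted 0.105), and r was -0.969 without those 2 libraries. Series B, C, D and E and the 10 most abundant tags gave adjusted exact permutation p-values between 0.11 and 0.52 for r and between 0.105 and 0.56 for rho. Without the libraries at 33 and 760, r went from -0.399 to -0.986 for series B and from 0.778 to 0.56 for series C. For series D it went from -0.339 to 0.178, and for series E from -0.584 to 0.20. For the 10 most abundant tags it went from -0.761 to -0.427. An r over the 4 libraries left carries little weight for any of the 9 relations. These relations were not tested within the 4 libraries of equal light alone.

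A bend in the response was called in 274 tags. In 119 of them the fitted curve bent downward, and 85 of these had their highest value at 164, 17 at 98, and 1 each at 33 and 760. In the other 155 it bent upward, and 112 of these had their lowest value at 164 and 31 at 98. The balance depended on scaling: median-of-ratios scaling gave 116 downward and 60 upward bends, and quantile normalization 105 and 55. Of the tags with an upward bend 149 belonged to series A and 6 to the plasmids, an odds ratio of 0.30 for the plasmids (95% interval 0.11 to 0.68; Fisher's exact test, two-sided, p = 0.0011, adjusted 0.0022). Of those with a downward bend 106 belonged to series A, 8 to series F, 4 to series G and 1 to series C. The odds ratio for the plasmids was 0.95 (0.49 to 1.72; Fisher's exact test, p = 1). Because tags are not independent, the p-value for upward bends is too small. Both odds ratios were worked out only in the fit as reported, and expression level was not taken into account. The count of bends rested on 2 libraries. It was 1 without the library at 33 and 2 without the library at 164. By comparison, it was 134 without 98, 164 without 395, 337 without 610 and 165 without 760. Limma without both the variance trend and the robust fit called 0 bends, with 747 tags at an unadjusted p under 0.05, against 855 in the fit with both.

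Between single libraries, which allow no test, 272 tags were at least 2-fold higher and 346 at least 2-fold lower at 760 than at 33. Which side was larger depended on scaling, since scaling to equal totals gave 349 higher and 257 lower. At 395, the highest level with equal light, 190 tags were higher and 404 lower than at 33, or 244 and 317 after scaling to equal totals. Most of this difference lay among weakly expressed tags. Among tags with a mean of at least 50 in the pair, 146 were higher and 150 lower at 760 than at 33, and 111 were higher and 151 lower at 395 than at 33. The largest folds of (value + 1) in this class were 7.58 higher and 36.7 lower at 760, and 5.74 higher and 144 lower at 395. The fold of 144 was that of A1476, from 431 at 33 to 2 at 395, and so rests on a value near the lowest possible. At 760 this tag stood at 19. Of the tags at least 2-fold lower at 760 than at 33, 77 were plasmid tags and 33 of these belonged to series F, where 3 tags were higher. Of those at least 2-fold higher, 21 were plasmid tags.

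Going from 395 to 760, 124 tags were at least 2-fold higher and 31 lower, and 23 and 3 of these had a mean of at least 50. Among tags of that level, steps between neighbouring libraries left 9.26% at least 2-fold apart from 33 to 98, 1.11% from 98 to 164, 4.85% from 164 to 395, 2.66% from 395 to 610 and 3.11% from 610 to 760. Scatter at low values was wide: between 395 and 760, 24.9% of the tags with a mean under 10 differed 2-fold or more when no floor of 10 was set, compared with 0.385% of the tags with a mean of 500 or more. The median log2 ratio of all tags was -0.02 from 33 to 760, -0.13 from 33 to 395 and 0.06 from 395 to 760.

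**Figure D4:**
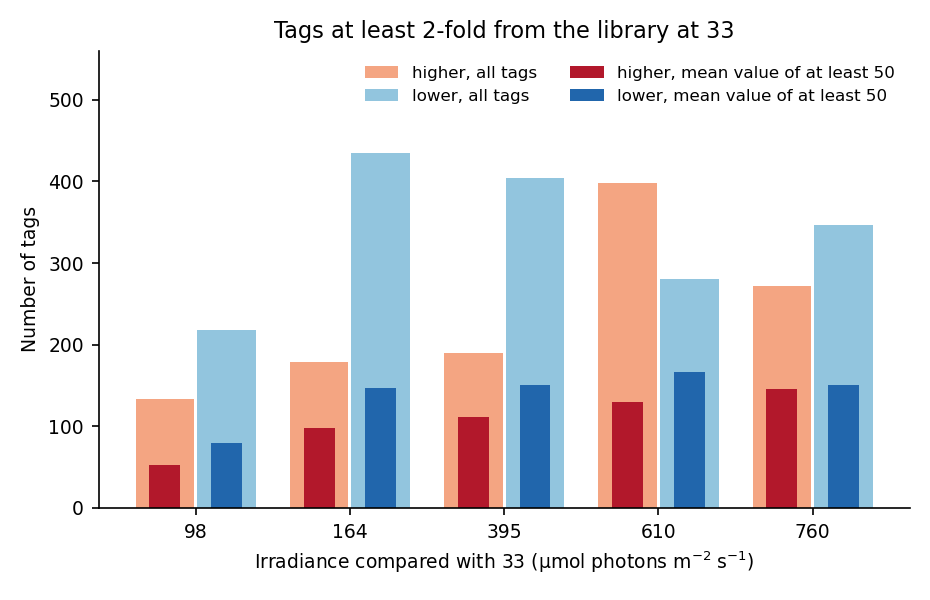
Number of tags at least 2-fold higher (red shades) or lower (blue shades) than in the library at 33, for each other irradiance, with wide pale bars for all tags and narrow dark bars for tags with a mean value of at least 50 in the pair. At 610, 398 tags are higher and 280 lower, while among tags with a mean of at least 50 these numbers are 130 and 167.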

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

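Quantile normalization, the minimum mean of 100, the share without a run, estimated correlations with libraries left out and the permuted orders were chosen after seeing the data; the other settings were fixed before. Of 100 orders of the irradiance values, the real one included, only the real one gave as many as 163 trend calls (at most 32 in another). This argues against chance ordering of trends. It cannot separate irradiance from anything else that follows the same order, such as the summed values. Bends numbered 274 (other orders: median 0), arguing against chance. The next highest (257) had a squared term correlated at -0.919 with real log2 irradiance. Rising tags numbered 136 after scaling to equal totals, 11 without limma's variance trend and robust fit, 44 on ranks of irradiance, 32 with a term for unequal light and 9 in the 4 libraries with equal light. Falling tags numbered 26 without both, 50 on linear irradiance, 51 on ranks and 28 with equal light alone. Leaving out 1 library gave 11 to 177 rising tags, 27 to 139 falling tags and 1 to 337 bends. Bends numbered 176 with median-of-ratios scaling (60 upward, 116 downward), 0 without the variance trend and robust fit, 160 after quantile normalization (55, 105) and 179 among tags with a mean of at least 100. Of the 6 tag series tested, 2 passed in the fit as reported (A and F), 2 with equal light alone (D and F), 1 with a term for unequal light, 0 with an estimated correlation and 1 to 3 with 1 library left out. The slopes of the 4 named tags stayed past the threshold in 65 of 76 settings and kept their sign in all 76. Of the 11 exceptions 8 were of A1476, and its limma adjusted p ranged from 0.017 to 0.24. Calls and signs that held say little, since the 4 tags had been picked for steep called slopes in the same libraries. The camera calls of the tag series kept their side of the threshold in 109 of 121 settings, most of them for series that had not passed. The 8 lost calls were all of series A and F, the 2 that had passed, and 4 calls were gained by other series. Among tags with a mean of at least 100, series F missed it (camera adjusted p = 0.074) and series G passed it (0.044). With the 10 most abundant tags left out of the total, 1 of 7 share correlations lost its call, series A (adjusted exact permutation p = 0.069). Without its run of 8 tags, picked as falling, the r of series G was 0.145. Counts of 2-fold differences moved with scaling and with low values. Equal totals gave 349 higher and 257 lower at 760 than at 33, and median-of-ratios scaling 248 and 310 at 395 than at 33. A floor of 50 gave 177 higher and 185 lower at 760 than at 33, 197 lower at 395 than at 33, and 34 higher and 4 lower at 760 than at 395. A pseudocount of 10 gave 177 and 211 at 760 against 33, 124 and 229 at 395 against 33, and 39 and 7 at 760 against 395. Without a floor, 62 tags were lower at 760 than at 395. Settings that need counts (DESeq2, trimmed-mean scaling, voom) and the removal of ribosomal and transfer RNA, whose tags are not identified here, were not run. No paired analysis was possible because each irradiance has 1 library. The missing depth and the single library per level limit all values, most of all those under about 25.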

Other observations

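The tests in this part were all chosen after the results they bear on had been seen. Many of the 163 tags with a trend lay side by side. In all, 64 of them formed 24 runs of at least 2 consecutive tags called in the same direction. The longest run held 8 tags of series G that fell, G0036 among them, with a median value of 660 at 33, 118.5 at 164, 33.5 at 395 and 44.5 at 760. A run of 6 tags of series A fell from a median of 376 at 33 to 158 at 164 and 100 at 760. Another run of 5 tags of series A rose from 636 to 1162 and 1857 at the same levels. Runs of 3 tags fell in series A, from 1350 to 162 and from 452 to 111 between 33 and 760, and in series F, from 42 to 5.

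Neighbouring tags called in the same direction numbered 40 of 3137 adjacent pairs, against a median of 5 and at most 13 in 1000 shuffles of the calls within series. Across tags, slopes of adjacent tags correlated at 0.319, those 10 apart at 0.083 and those 50 apart at -0.018. Similar expression levels of neighbours do not account for the correlation of 0.319. It was 0.316 once the median slope of tags of like level had been taken off. The shuffles of calls did not match tags by level, so like levels of neighbours stay open for the 40 pairs. A slow gradient along the replicon is argued against by the value at 50 tags. Shared transcription units are a candidate explanation that these numbers go with, as a hypothesis, since strand and gene distance were not used here and reads spilling over gene borders stay open.

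The excess of the library at 610 among weakly expressed tags was weighed in the same way, against the mean of the libraries at 395 and 760. A scaling factor of the whole library is argued against, since the median log2 ratio was 0.65 in the lowest quartile of tags (95% bootstrap interval 0.58 to 0.72) and -0.08 in the highest (-0.11 to -0.05). Deeper sequencing with values of 0 raised to 1 is argued against by the second quartile, far from 1, where the ratio was 0.20 (0.17 to 0.24). Tags were sorted by the same mean that formed the ratio, which can by itself raise the lower quartiles. The intervals hold no error between libraries. The same measure in the lowest quartile, each library against its neighbours in irradiance, was 0.08 at 98, -0.17 at 164 and -0.38 at 395. For 395 the library at 610 is itself a neighbour. An additive background that follows DNA copies, such as genomic DNA carried into the RNA, stays open. The excess was 5.5 units in the lowest and 4.5 in the second quartile, and 65, 15.2 and 24.5 units in the small plasmid series C, D and E, against 5 in series A. It was, however, 0.5 units in the third quartile (-1 to 1.5) and -14.5 in the highest, and in plasmid series F and G it was 4.5 and 4, no higher than in series A. Such a background would give these values only with a further assumption, a rescaling of the library and low copy numbers of F and G, and neither is known here. A response of these tags to the light at 610 stays open as untested, because that level has 1 library.

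The sample code of the library at 610 ends in 8, while those of the other libraries run from 1 to 5 in order of irradiance. The labels do not say what the codes mean. If they follow an order of sampling or handling, its effects cannot be told apart from those of irradiance here. The median value of the 3 tags of series B was 65 at 33, 81 at 98, 47 at 164, 22 at 395, 155 at 610 and 31 at 760.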
